A study of Homo sapiens with 4 samples.

How the data were processed

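RNA was sequenced from 4 HK-2 samples, 2 controls and 2 treated with TGF-β1. Per the labels' protocols, cells were deprived of serum for 24 h, TGF-β1 was given at 20 ng/mL for 24 h, and 4-thiouridine was present at 100 μM for the final 20 h. This text is the same for all 4 samples; controls, told apart by title and treatment label, were taken to have had every step but TGF-β1. The molecule is given as total RNA, and enrichment of labelled RNA is not mentioned in the sources used here. RNA was extracted with TRIzol, and libraries were made with a directional (strand-preserving) NEBNext kit, per the labels' protocols. Samples were assigned to groups and replicate numbers by their titles.

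The authors deposited 1 table of RPKM values, with 25609 genes named by versioned Ensembl identifiers and 4 columns. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.1a, DESeq2 and the build hg38, without giving their roles or order. The gene annotation release, the strand setting of the counting, any filter on genes and the tool that made the RPKM values are not given in the sources used here. Identifiers were paired with symbols through a table of gene names, which held 25312 of them. Coordinates, gene types and exon lengths came from GENCODE release 29 on hg38, where 23853 identifiers (93.1%) had the same version, 1650 another version and 106 were not found.

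No value in the table is 0. Multiplied by exon length, the values of each library fell on a whole number of reads plus 0.5, times a constant of that library. With a tolerance of 0.01 read this held for 100% of the genes whose identifier had the same version in GENCODE 29. For 1621 genes with another version the length was inferred from the values. Whole reads were recovered for 25474 genes (99.5%), of which 2281 had 0 reads in all 4 libraries. They summed to 3330021 and 4791914 reads for control replicates 1 and 2 and to 4629456 and 5440187 reads for TGF-β1 replicates 1 and 2. The constants imply that the authors scaled by 3390863, 4700111, 4156179 and 4708954 reads in the same order. These library sizes are 1.02, 0.981, 0.898 and 0.866 times the recovered totals, so the scaling lowered the divisor of the TGF-β1 libraries relative to that of the controls, which raises their RPKM values. At this depth a gene of low expression rests on few reads: MIR17HG had 11, 25, 21 and 21. Mitochondrial genes took 8.81% to 9.84% of the recovered reads and the 10 most abundant genes 9.51% to 10.4%.

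The main comparison used RPKM as deposited, without further scaling, because the values are not counts. Genes with a mean RPKM of at least 0.5 over the 4 libraries (16590 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with lmFit and eBayes with a variance trend. P values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p below 0.05 are called changed. Fold changes quoted as log2 are on this scale and understate the change of weakly expressed genes, whereas ratios quoted as fold are ratios of group means of RPKM. Values with ± are means and SDs of 2 libraries. Where a group had 0 reads in both libraries, the bound on the fold change sets that group at 3 reads in total and takes the reads of the other group as exact. Where it had 1 to 3 reads, the ratio is given with its 95% counting interval.

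Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 30 lists, and again with an estimated correlation. With limma's fry, the test is whether the genes of a list move on balance in a single direction, without comparing them with other genes. The lists covered TGF-β signalling, matrix, contractile and mesenchymal genes, epithelial and tubular genes, injury, Hippo and YAP genes, microRNA biology, cell cycle, stress, interferon, metabolism and markers of other cell types. They, the tests, the alternatives other than the 3 named as later additions, and the rule for naming genes were fixed before the data were examined. The rule names FRMD6, MIR17HG, SMAD7, COL1A1, FN1, CDH1, VIM and ACTA2. It adds the 8 largest rises and the 8 largest falls among called genes with a mean RPKM of at least 1 and no overlap between the groups. In each list it takes the 3 called members with the smallest p, or where none passed the 1 member with the smallest p. Some genes that meet the rule are not reported here. Other members of a list are named only to complete a small count, and these were chosen after their values were seen.

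Matches to the seed of miR-17 and miR-20a were searched in the longest annotated 3′ UTR of each gene in GENCODE 29, as the 7-base word GCACTTT. Fold changes were centred on the median of their bin of UTR length and expression. The medians of the centred values with and without a match were compared by 10000 permutations within bins, and with 416 control words of the same base composition.

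The procedure was tested on simulated counts drawn for 16390 genes from the means and library sizes of these 4 libraries, with 200 genes changed by 2-fold or 4-fold. The main test called 109 genes, of which 11 (10.1%) were false, more than the nominal 5%. It recovered 25% of the 2-fold and 73% of the 4-fold changes. Limma's voom on the same counts called 156 genes, 1.28% of them false, and recovered 67% and 87%. Neither called any of 20 unchanged gene lists. The genes were simulated independently, so this check could not show false list calls that arise from correlation between genes. It was a single draw with the same dispersion (variance beyond counting noise) of 0.00457 for every gene. Differences in variance between genes were not simulated, so the shares of false calls may differ in the real data.

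The alternatives fixed in advance were pseudocounts of 0.1 and 1, no expression filter, a mean RPKM of at least 2, median-of-ratios scaling, quantile normalisation, upper-quartile scaling, no variance trend, robust empirical Bayes, the replicate number as a block, and leaving out each library in turn. Leaving out a library leaves a group with 1 sample, which is then assumed to vary like the other group. A threshold of 1 on the absolute log2 fold change was also among them. Limma's voom on the recovered reads, the RPKM values without a further pseudocount, and scaling each library by its total of recovered reads were added after seeing the data, as were 5 gene lists described among the additional observations. Pearson correlations of log2 values between replicates were 0.966 for the controls and 0.971 for TGF-β1. Recovered reads of replicates differed by more than counting noise, with chi-square over degrees of freedom of 2.02 and 1.94, which argues only against 1 library having been deposited under 2 names. The replicates were treated as separate because the labels list them as separate samples. Analyses outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.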

Results

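Total RNA was sequenced from HK-2 cells, a line of human kidney proximal tubule epithelium immortalised with papillomavirus oncogenes, with and without transforming growth factor β1 (TGF-β1). TGF-β1 is a cytokine that drives matrix production and loss of epithelial features in tubular cells. The 4 libraries comprised 2 controls and 2 samples given TGF-β1 at 20 ng/mL for 24 h after 24 h without serum. The protocol also used 4-thiouridine, a uridine analogue taken up into newly made RNA, at 100 μM for the last 20 h. The labels carry 1 treatment protocol, with TGF-β1 in it, for all 4 samples, and the controls were taken to have had the same steps without TGF-β1. The labels give the molecule as total RNA, and whether labelled RNA was enriched is not given in the sources used here. Expression was given by the authors as RPKM (reads per kilobase of exon, scaled to library size) for 25609 genes. The read counts recovered from these values summed to 3330021 and 4791914 for control replicates 1 and 2, and to 4629456 and 5440187 for TGF-β1 replicates 1 and 2. Between 21.3% and 25.8% of genes had 0 reads in a given library. The labels call the samples replicates of a group without naming separate cultures, so p-values measure only the spread between these libraries, which may be technical.

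The design holds 1 comparison, TGF-β1 against control, and asks which transcripts of the tubular cell respond to the cytokine. The series title adds a narrower question, whether FRMD6, a FERM-domain protein upstream of the Hippo kinases, is held down by miR-17 and miR-20a in renal epithelium. FRMD6 rose with TGF-β1. At a preset correlation between genes, lists of TGF-β signalling, extracellular matrix and contractile genes were higher than other genes, and lists of tubular identity, interferon response and S phase genes were lower. All of these list calls were lost by camera with an estimated correlation (adjusted p = 0.375 to 0.712). That test rests on 2 residual degrees of freedom and could hardly pass any list. For SMAD targets, S phase and interferon genes the estimate (0.0095, 0.0099 and -0.0028) was no larger than the preset 0.01. Correlation between genes therefore does not account for the loss in those lists. Not every member of a list passed. Of 16590 genes tested, 1513 changed at an adjusted p below 0.05 (limma, Benjamini-Hochberg adjustment), 1015 higher and 498 lower with TGF-β1. Of these, 634 differed by at least 1 on the log2 scale, 395 higher and 239 lower. Protein-coding genes made up 883 of the higher and 425 of the lower genes. In each of the 1513 genes both TGF-β1 libraries lay on the same side of both control libraries, which selection by p value all but ensures. Among all tested genes 54.1% were so arranged, against 33.3% by chance. Higher genes made up 67.1% of the calls with the authors' scaling, 62.2% with median-of-ratios scaling and 59.7% with upper-quartile scaling. Their share was 50.4% after quantile normalisation and 42.6% when each library was scaled by its total of recovered reads (655 higher and 883 lower). That last scaling moved the median log2 fold change of all tested genes by -0.15, from 0.03 to -0.13. The count of calls fell to 574 without TGF-β1 replicate 2, 739 without TGF-β1 replicate 1, 999 without control replicate 1 and 1138 without control replicate 2. It fell to 424 when the variance was not modelled as a function of expression.

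**Figure D1:**
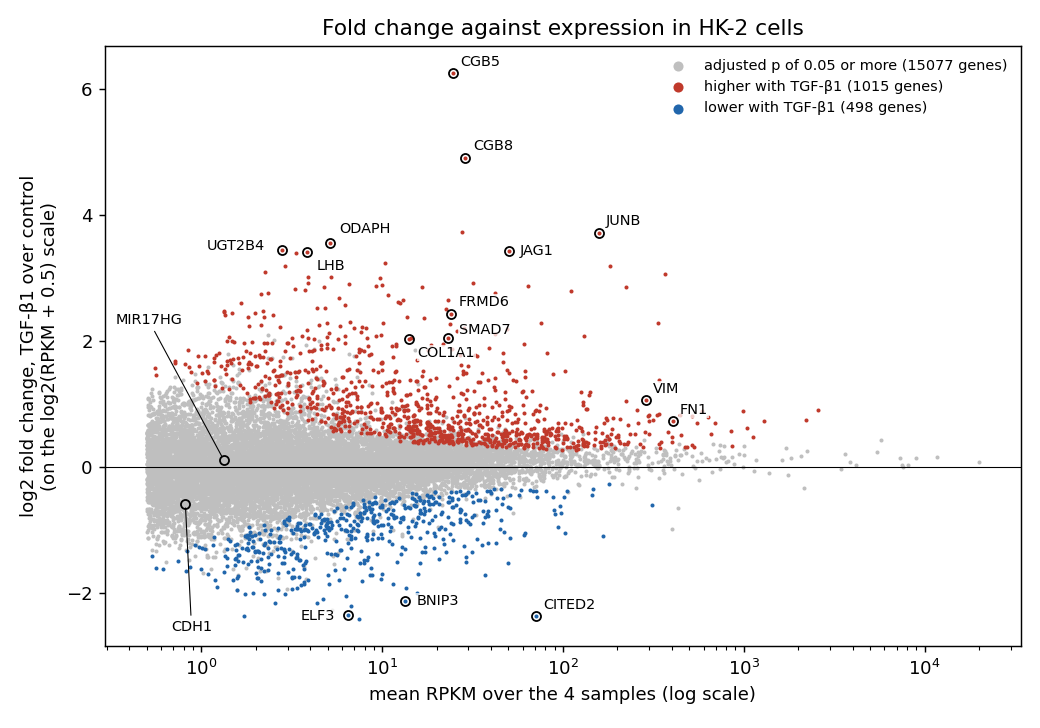
Each point is 1 of the 16590 tested genes, with mean RPKM over the 4 libraries on a log axis and the log2 fold change of TGF-β1 over control on the log2(RPKM + 0.5) scale. Red points are the 1015 genes that passed as higher, blue points the 498 that passed as lower and grey points the rest, with some named genes circled: FRMD6 lies at 2.44, JUNB at 3.73 and MIR17HG at 0.12. The share of higher calls depends on the scaling and falls to 42.6% with scaling by total recovered reads.

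FRMD6 (ENSG00000139926.15, hg38 chromosome 14, 51489100 to 51730727, plus strand) rose from 7.15 ± 0.35 RPKM in controls to 41.1 ± 0.99 RPKM with TGF-β1 (SD, n = 2 per group), a 5.74-fold difference. Its log2 fold change was 2.44 with a standard error of 0.08 and a 95% confidence interval of 2.23 to 2.65 (adjusted p = 0.000914, limma). The recovered reads were 220 and 327 in the controls and 1580 and 1852 with TGF-β1, and the log2 fold change stayed between 2.27 and 2.52 under all 17 alternative settings. The antisense transcript FRMD6-AS1 overlaps the gene and had 5 and 3 reads in controls and 9 and 18 with TGF-β1 (adjusted p = 0.201). MIR17HG (ENSG00000215417.12, chromosome 13, 91347820 to 91354579), the primary transcript that carries miR-17 and miR-20a, measured 1.26 ± 0.41 RPKM in controls and 1.39 ± 0.12 RPKM with TGF-β1. Its log2 fold change was 0.12 with a 95% confidence interval of -0.55 to 0.80 (adjusted p = 0.829, limma), so no difference was detectable at a depth of 11 to 25 reads per library. Its sign changed without control replicate 1 (-0.12) and with scaling by total recovered reads (-0.01). Mature microRNAs were not analysed here.

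**Figure D2:**
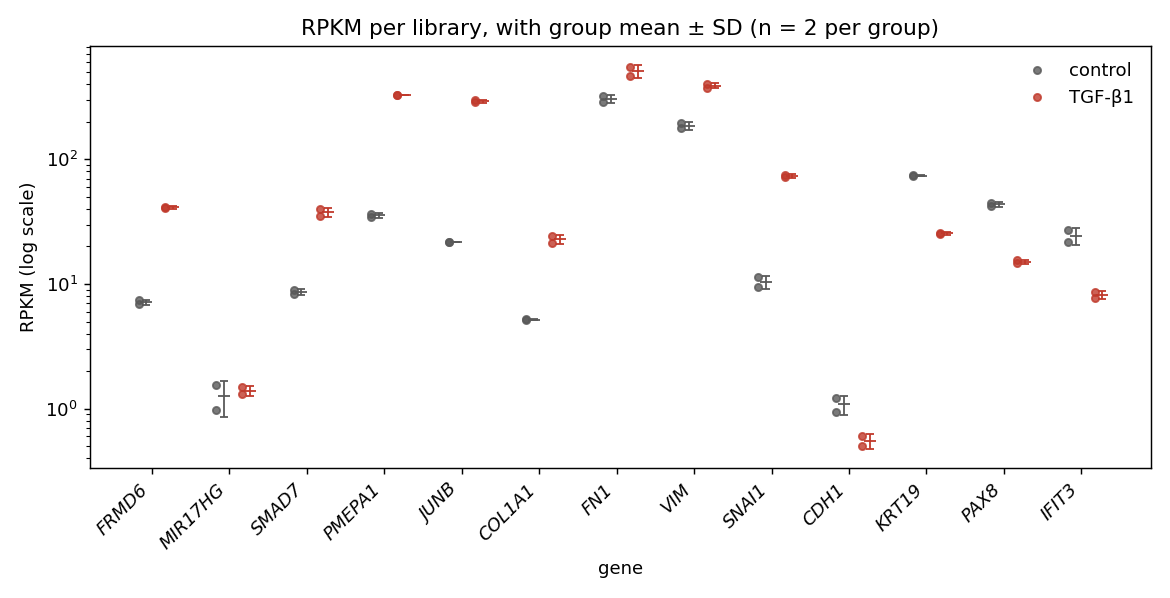
RPKM (log axis) of selected genes in each library, with control in grey and TGF-β1 in red; points are libraries, and the bar beside each pair is the group mean ± SD (n = 2). FRMD6 moves from 7.15 to 41.1 RPKM, PMEPA1 from 35.6 to 329 RPKM and KRT19 from 73.7 to 25.4 RPKM, whereas the libraries of MIR17HG overlap.

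The 8 largest rises among genes with a mean RPKM of at least 1 included CGB5, CGB8, JUNB, ODAPH, UGT2B4, JAG1 and LHB. CGB5 and CGB8 encode the β subunit of chorionic gonadotropin and LHB that of luteinising hormone, and the 3 genes lie in 1 cluster on chromosome 19 between 49015980 and 49058860. CGB5 had 0 reads in both controls against 163 and 205 with TGF-β1, which made it at least 112-fold higher, measured against a floor of 3 reads over the control group. LHB likewise went from 0 reads to 16 and 17 (at least 10.0-fold higher), and UGT2B4, a glucuronosyltransferase, from 0 reads to 60 and 62 (at least 37.1-fold higher). CGB8 rose from 3 and 6 reads to 191 and 246. Reads of the CGB genes cannot be assigned firmly to single copies, because 86.0% of the 50-base words of CGB5 and 82.8% of those of CGB8 also occur in another family member. LHB shares 0.520% of its words. UGT2B4 also belongs to a family of similar genes. JAG1, a Notch ligand, rose 11.1-fold from 8.29 ± 3.0 to 92.1 ± 12 RPKM. ODAPH, an enamel matrix gene, went from 3 and 2 reads to 68 and 114. Floors cover only the counting error of the group with 0 reads, and counting intervals cover counting error only.

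The 8 largest falls included ENSG00000255446, CITED2, ELF3, LINC02274, MAL, ENSG00000274758 and BNIP3. CITED2, a CBP/p300-binding transcriptional coregulator, fell from 119 ± 13 to 22.8 ± 1.6 RPKM (log2 fold change -2.36). ELF3, an epithelial ETS factor, fell from 11.1 ± 1.3 to 1.80 ± 0.36 RPKM (-2.34), and MAL, a raft protein of apical sorting, from 7.39 ± 1.4 to 1.29 ± 0.54 RPKM (-2.16). BNIP3, a mitochondrial protein induced by hypoxia, fell from 22.2 ± 3.8 to 4.67 ± 0.32 RPKM (-2.12). The non-coding LINC02274 fell from 11.4 ± 3.5 to 2.08 ± 0.77 RPKM (-2.21). ENSG00000255446 and ENSG00000274758 are antisense transcripts with 0 reads in both TGF-β1 libraries. Against a floor of 3 reads in that group, with the control reads taken as exact, they were at least 4.38-fold and at least 2.19-fold lower. Whether strand was used in counting is not given in the sources used here, so their reads cannot be told from those of genes on the opposite strand. The call for ENSG00000274758, which rests on 4 and 2 control reads, was lost without control replicate 1 (adjusted p = 0.0579), without TGF-β1 replicate 1 (0.0787) and without TGF-β1 replicate 2 (0.0955). LINC02274, MAL and ENSG00000274758 did not pass without the variance trend (adjusted p = 0.0652, 0.0568 and 0.099).

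Of 25 tested targets of TGF-β and SMAD signalling, 17 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 0.99. PMEPA1, a feedback inhibitor of the pathway, rose 9.24-fold from 35.6 ± 1.5 to 329 ± 1.0 RPKM, and JUNB, an AP-1 subunit, rose 13.5-fold from 21.7 ± 0.038 to 293 ± 8.1 RPKM. SMAD7, the inhibitory SMAD, rose 4.34-fold from 8.65 ± 0.43 to 37.6 ± 3.4 RPKM. The list was higher than other genes by limma's camera with a preset correlation of 0.01 (adjusted p = 4.00e-17, and adjusted p = 0.375 with an estimated correlation). Among 21 ligands, receptors and binding proteins of the family, 9 rose and 3 fell (12 and 4 adjusted over the list alone; median log2 0.50). TGFB1 itself rose 4.30-fold to 211 ± 7.0 RPKM, INHBA, the activin A subunit, 8.05-fold to 56.9 ± 0.37 RPKM, and FSTL3, an activin-binding follistatin relative, 3.56-fold to 128 ± 9.3 RPKM. The 3 that fell were the receptor gene TGFBR2 (log2 -0.63), SMAD3 (-0.51) and GDF15 (-0.73). Scaled by total recovered reads, 8 rose and 4 fell, with a median of 0.32. This list was also higher by camera (adjusted p = 0.00613, and adjusted p = 0.439 with an estimated correlation). Of the 30 lists, 18 passed camera at the preset correlation. All 18 missed the threshold when the correlation was estimated from these 4 libraries, where 2 residual degrees of freedom remain. Even the SMAD target list missed it, although its estimated correlation (0.0095) was no larger than the preset 0.01. That test had little power, so a miss by it says little about a list.

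**Figure D3:**
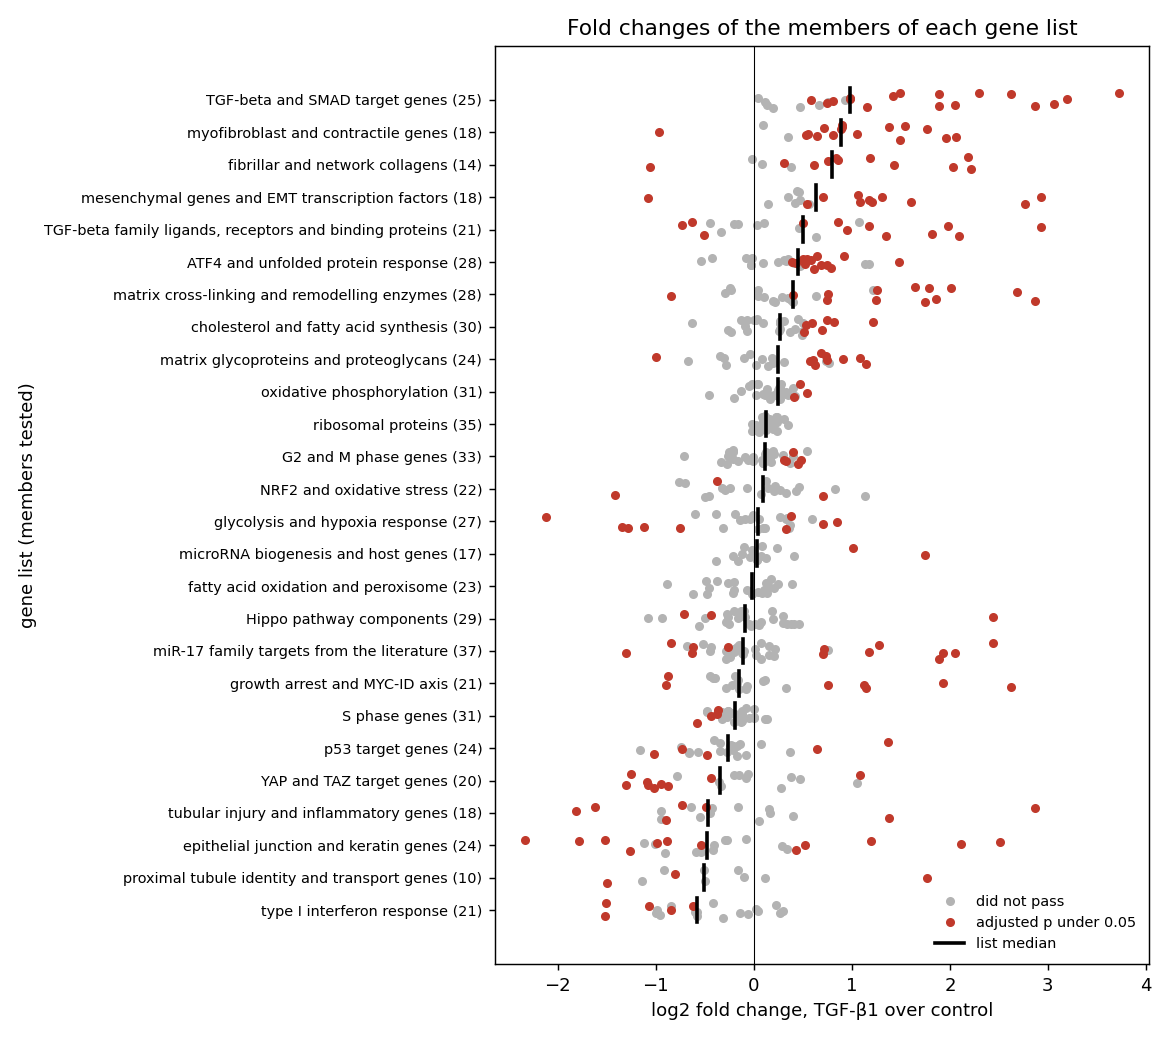
Log2 fold change of TGF-β1 over control for the tested members of each of the 26 gene lists with at least 5 tested members, sorted by median; red points are members with an adjusted p below 0.05, grey points the others and black bars the list medians. The medians run from -0.58 for interferon response genes to 0.99 for TGF-β and SMAD targets; with scaling by total recovered reads the medians shift down together and that of the ribosomal proteins changes from 0.12 to -0.06.

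Of 14 tested collagens, 10 rose and 1 fell (10 and 1 adjusted over the list alone; median log2 0.80). COL1A1 (chromosome 17, 50183289 to 50201632) rose 4.41-fold from 5.19 ± 0.030 to 22.9 ± 2.0 RPKM, and COL5A1 rose 5.51-fold from 2.15 ± 0.070 to 11.8 ± 0.28 RPKM. COL8A1, a short-chain network collagen, fell from 32.2 ± 0.33 to 15.2 ± 0.10 RPKM (log2 -1.06). Among 24 glycoproteins and proteoglycans, 9 rose and 1 fell (11 and 4 adjusted over the list alone; median 0.25). Fibronectin (FN1) rose 1.67-fold from 304 ± 23 to 507 ± 62 RPKM (log2 0.74, adjusted p = 0.0203, and log2 0.45 after quantile normalisation), SPARC, a collagen-binding protein, 1.88-fold to 335 ± 19 RPKM, LAMB3, a laminin chain, 2.28-fold to 18.9 ± 1.1 RPKM, and IGFBP3, which binds insulin-like growth factors, 2.14-fold to 39.8 ± 0.65 RPKM. The member that fell was LAMA3, another laminin chain (-0.99). Of 28 cross-linking and remodelling enzymes, 12 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.40). ADAM19, a metalloprotease, rose 8.71-fold to 10.3 ± 0.15 RPKM, the transglutaminase TGM2 3.56-fold to 42.1 ± 4.4 RPKM and the collagen prolyl hydroxylase P4HA2 3.60-fold to 18.1 ± 1.1 RPKM, whereas ADAMTS1 fell (-0.84). Camera gave adjusted p = 1.57e-06, 0.0121 and 4.39e-07 for the 3 lists in this order, against adjusted p = 0.438, 0.712 and 0.445 with an estimated correlation. With scaling by total recovered reads 8 glycoprotein genes rose and 5 fell (median 0.08), and 11 enzyme genes rose and 1 fell (median 0.22). The glycoprotein list missed the threshold among genes with a mean RPKM of at least 2 (adjusted p = 0.0609). The FN1 call was lost without control replicate 1 (adjusted p = 0.0555) and without the variance trend (0.0993), and the calls of SPARC and LAMB3 without that trend (0.0586 and 0.0568).

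Among 18 myofibroblast and contractile genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone; median log2 0.89). TAGLN2, a transgelin, rose 2.60-fold from 188 ± 20 to 488 ± 8.5 RPKM, PDLIM7, an actin-associated LIM protein, 2.85-fold to 74.3 ± 0.0018 RPKM and TNS1, a focal adhesion tensin, 4.73-fold to 13.7 ± 1.9 RPKM. MYLK, the myosin light chain kinase gene, fell (-0.97). ACTA2, which encodes α smooth muscle actin, was below the expression filter with 1 and 3 reads in the controls and 0 in both TGF-β1 libraries, so no change in it was detectable at this depth. Among 18 mesenchymal genes and transcription factors of epithelial-mesenchymal transition, 10 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.64). Vimentin (VIM) rose 2.10-fold from 185 ± 12 to 389 ± 19 RPKM, SNAI1, a repressor of E-cadherin, 7.07-fold from 10.4 ± 1.2 to 73.6 ± 2.7 RPKM and the integrin subunit ITGA5 2.17-fold to 27.0 ± 2.1 RPKM. AXL, a receptor tyrosine kinase, fell from 82.7 ± 8.8 to 39.0 ± 4.2 RPKM (-1.08). Both lists were higher by camera (adjusted p = 1.19e-11 and 1.15e-07, and adjusted p = 0.439 for both with an estimated correlation).

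Epithelial and tubular genes moved in both directions, with more falls than rises. E-cadherin (CDH1) measured 1.08 ± 0.19 RPKM in controls and 0.551 ± 0.074 RPKM with TGF-β1 and did not pass (log2 -0.59, 95% confidence interval -1.25 to 0.08, adjusted p = 0.251), on 14 to 27 reads per library. Of 24 junction and keratin genes, 5 rose and 7 fell (5 and 10 adjusted over the list alone; median -0.47). KRT19 fell from 73.7 ± 0.72 to 25.4 ± 0.63 RPKM (-1.52), while KRT7 rose 6.09-fold to 38.8 ± 4.9 RPKM, the desmosomal protein DSP 4.46-fold to 68.5 ± 9.1 RPKM, and KRT8, KRT18 and CLDN4 by 1.19, 0.43 and 0.53 on the log2 scale. Of 10 proximal tubule identity and transport genes that could be tested, 1 rose and 2 fell (1 and 4 adjusted over the list alone; median -0.50). PAX8, the renal lineage transcription factor, fell from 43.5 ± 1.8 to 15.1 ± 0.62 RPKM (-1.50) and the brush-border peptidase DPP4 from 13.9 ± 0.74 to 7.74 ± 0.36 RPKM (-0.80), while ASS1, the arginine synthesis enzyme, rose 3.82-fold to 11.3 ± 2.0 RPKM. Of 18 tubular injury and inflammatory genes, 2 rose and 5 fell (3 and 9 adjusted over the list alone; median -0.47). The 2 that rose were the cytokines IL11, 7.36-fold from 53.4 ± 3.6 to 393 ± 0.58 RPKM, and LIF, 2.62-fold to 79.7 ± 1.5 RPKM. CSF1, the macrophage growth factor, fell from 12.3 ± 1.6 to 3.15 ± 0.28 RPKM (-1.81), and LCN2 (-1.62), the injury marker HAVCR1 (-0.89), NFKBIA (-0.73) and ICAM1 (-0.49) also fell. By camera the 3 lists were lower (adjusted p = 0.0121, 0.00442 and 0.0130, and adjusted p = 0.550, 0.439 and 0.439 with an estimated correlation). Scaled by total recovered reads, 3 junction and keratin genes rose and 8 fell (median -0.59), 1 proximal tubule gene rose and 4 fell (-0.64), and 2 injury genes rose and 7 fell (-0.61). The epithelial list lost its call among genes with a mean RPKM of at least 2 (adjusted p = 0.0734), without control replicate 2 (0.0602) and with scaling by total recovered reads (0.109), and the injury list without the expression filter (0.215), without control replicate 2 (0.0706) and with that scaling (0.0602). DPP4 did not pass without TGF-β1 replicate 2 (adjusted p = 0.0625) or without the variance trend (0.0652).

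FRMD6 was the only 1 of 29 tested Hippo pathway components that rose, and 2 fell (4 rose and 4 fell adjusted over the list alone). The 2 were AMOTL2, an angiomotin (66.1 ± 0.061 to 48.7 ± 3.6 RPKM, -0.44), and WWC1, known as KIBRA (10.0 ± 0.52 to 5.95 ± 0.80 RPKM, -0.71). Both calls were lost whichever library was left out, with adjusted p values up to 0.106 and 0.130, and the list did not pass camera (adjusted p = 0.301). Of 20 targets of the Hippo effectors YAP and TAZ, 1 rose and 8 fell (5 and 10 adjusted over the list alone; median -0.35). AJUBA, a LIM-domain scaffold, fell from 40.2 ± 0.15 to 16.6 ± 0.18 RPKM (-1.25) and GADD45A, a stress-response gene, from 24.0 ± 1.1 to 11.6 ± 0.017 RPKM (-1.02), while IGFBP3 rose. The list was lower by camera (adjusted p = 0.000645, and adjusted p = 0.493 with an estimated correlation). Among 37 published targets of the miR-17 family, 8 rose and 5 fell (9 and 5 adjusted over the list alone), with a median log2 of -0.11 and a mean of 0.16, and camera found no shift (adjusted p = 0.866, direction down). By fry the list leaned towards higher without passing (adjusted p = 0.0513). FRMD6, SMAD7 and CCND1, the cyclin D1 gene (4.26-fold, 3.17 ± 0.29 to 13.5 ± 0.13 RPKM), had the smallest p values of the risers. Of these, FRMD6 is the gene of the series title, and SMAD7 is also in the list of SMAD targets. The 5 that fell were F3 (-1.31), HIF1A (-0.84), TGFBR2 (-0.63), SQSTM1 (-0.62) and TXNIP (-0.27). Of 17 genes of microRNA biogenesis and host transcripts, MIR22HG rose 2.09-fold to 11.6 ± 0.81 RPKM and MIR31HG went from 1 read in each control to 9 in each TGF-β1 library, a ratio of 8.21 with a 95% counting interval of 1.97 to 73.0. The remaining 15 did not pass (2 rose and 0 fell adjusted over the list alone), and the list did not pass camera (adjusted p = 0.866). Neither MIR22HG nor MIR31HG passed without TGF-β1 replicate 1 (adjusted p = 0.0751 and 0.0793) or TGF-β1 replicate 2 (0.0575 and 0.0694), and MIR22HG did not without the variance trend (0.0736).

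Of 31 S phase genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone; median -0.20). The histone mRNA-binding protein SLBP fell from 166 ± 3.7 to 123 ± 5.1 RPKM (-0.43), the licensing factor CDT1 from 119 ± 6.3 to 91.5 ± 2.8 RPKM (-0.37), DSCC1, a cohesion factor, from 9.65 ± 0.53 to 6.28 ± 0.059 RPKM (-0.58), and MCM6 by -0.37. The list was lower by camera (adjusted p = 2.16e-06, and adjusted p = 0.386 with an estimated correlation). Of 33 G2 and M phase genes, 5 rose and 0 fell (6 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.291). AURKB rose 1.32-fold to 152 ± 0.68 RPKM, CCNB1 1.37-fold to 117 ± 1.6 RPKM and PLK1 1.40-fold to 41.7 ± 2.2 RPKM, with UBE2C (0.33) and BIRC5 (0.31). With scaling by total recovered reads, 1 of these 33 genes rose and 3 fell, with a median of -0.07, and of the 31 S phase genes 0 rose and 10 fell, with a median of -0.38. Each call of SLBP, CDT1, DSCC1, AURKB, CCNB1 and PLK1 was lost without TGF-β1 replicate 2 (adjusted p = 0.0776, 0.132, 0.142, 0.0895, 0.0887 and 0.135). All but that of SLBP were also lost without TGF-β1 replicate 1 (0.0838, 0.140, 0.0777, 0.0699 and 0.0743), and all but that of AURKB without control replicate 1 (0.0583, 0.0915, 0.104, 0.0579 and 0.0741). Without control replicate 2 those of DSCC1 (0.0671) and AURKB (0.0662) were lost. Without the variance trend SLBP, CDT1, DSCC1, AURKB, CCNB1 and PLK1 did not pass (adjusted p = 0.146, 0.190, 0.0935, 0.165, 0.150 and 0.150). The calls of AURKB, CCNB1 and PLK1 also depended on the scaling. After quantile normalisation none of the 3 passed (adjusted p = 0.267, 0.0636 and 0.0611), with log2 values down from 0.40 to 0.15 for AURKB and from 0.45 to 0.21 for CCNB1. With scaling by total recovered reads AURKB (0.112) and PLK1 (0.0629) did not pass, nor did PLK1 with median-of-ratios scaling (0.0622) or AURKB with upper-quartile scaling (log2 0.34, adjusted p just over 0.05).

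Among 21 genes of growth arrest and the MYC and ID axis, 5 rose and 2 fell (6 and 3 adjusted over the list alone). The cyclin-dependent kinase inhibitor gene CDKN2B rose 6.86-fold from 3.10 ± 1.0 to 21.3 ± 0.81 RPKM, its neighbour CDKN2A 1.70-fold to 151 ± 0.78 RPKM, and CCND1, ID1 (log2 1.15) and ID3 (1.13) also rose. MXI1 (-0.90) and CDKN1C (-0.87) fell, and the list did not pass camera (adjusted p = 0.866, median -0.15, mean 0.18). Of 24 p53 targets, 2 rose and 3 fell (2 and 6 adjusted over the list alone; median -0.26). GADD45A and GDF15, a stress-induced TGF-β family member (122 ± 10 to 73.4 ± 1.9 RPKM, -0.73), fell together with PHLDA3 (-0.48), while SESN2, a stress-response sestrin, rose 1.57-fold to 43.5 ± 0.23 RPKM and TP53I3 rose (1.37). The list was lower by camera (adjusted p = 0.000413, and adjusted p = 0.439 with an estimated correlation). Of these 24 genes, 2 rose and 7 fell with scaling by total recovered reads (median -0.44). HK-2 cells carry the papillomavirus oncoprotein that degrades p53. Of 21 tested interferon response genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone; median -0.58). IFIT3 fell from 24.4 ± 3.8 to 8.19 ± 0.60 RPKM (-1.51), IFIT2, another antiviral tetratricopeptide protein, from 5.81 ± 0.034 to 1.72 ± 0.24 RPKM (-1.51), the oligoadenylate synthetase gene OAS3 from 9.10 ± 0.35 to 4.83 ± 0.29 RPKM (-0.85), and PARP9 (-1.07) and STAT2 (-0.62) also fell. Camera gave adjusted p = 2.42e-05, and adjusted p = 0.386 with an estimated correlation. OAS3 lost its call without control replicate 2 (log2 -0.81), TGF-β1 replicate 1 (-0.79) or TGF-β1 replicate 2 (-0.91). Without the variance trend OAS3, CDKN2A, SESN2 and GDF15 lost their calls (adjusted p = 0.061, 0.0635, 0.0767 and 0.0779).

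Of 28 tested genes of the ATF4 and unfolded protein responses, 13 rose and 0 fell (21 and 2 adjusted over the list alone; median log2 0.45). ATF4 itself rose 1.68-fold from 225 ± 6.9 to 377 ± 14 RPKM, the amino acid transporter SLC7A5 2.81-fold from 46.1 ± 0.28 to 130 ± 0.78 RPKM and the bZIP factor CEBPB 1.90-fold to 92.6 ± 2.1 RPKM (camera adjusted p = 6.55e-08, and adjusted p = 0.439 with an estimated correlation). After quantile normalisation ATF4 kept its call with a log2 of 0.44, against 0.74. Of the 28 genes, 9 rose and 0 fell with scaling by total recovered reads (median 0.28). Of 30 cholesterol and fatty acid synthesis genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.27). The desaturase SCD rose 1.77-fold to 380 ± 39 RPKM, fatty acid synthase (FASN) 1.45-fold to 67.5 ± 0.23 RPKM and the sterol carrier STARD4 2.67-fold to 5.12 ± 0.82 RPKM (camera adjusted p = 0.000846, and adjusted p = 0.493 with an estimated correlation). Of these 30, 5 rose and 1 fell with scaling by total recovered reads (median 0.09). STARD4 did not pass without control replicate 1 (adjusted p = 0.0552), TGF-β1 replicate 1 (0.106) or TGF-β1 replicate 2 (0.0597), nor FASN without TGF-β1 replicate 2 (0.0531). ATF4, CEBPB, SCD, FASN and STARD4 did not pass without the variance trend (0.0670, 0.0507, 0.0716, 0.101 and 0.0574). Of 31 oxidative phosphorylation genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.24): COX6C 1.39-fold, UQCRQ 1.33-fold and UQCRC1 1.47-fold. Camera placed that list higher (adjusted p = 0.000820, and adjusted p = 0.579 with an estimated correlation), but not after quantile normalisation (0.116). Each of these 3 genes lost its call without TGF-β1 replicate 2 (adjusted p = 0.104, 0.120 and 0.0929) and without control replicate 1 (0.0547, 0.0772 and 0.0703). COX6C and UQCRQ also lost theirs without TGF-β1 replicate 1 (0.107 and 0.0613), and UQCRQ without control replicate 2 (0.0506). Without the variance trend none of the 3 passed (adjusted p = 0.12, 0.17 and 0.14). After quantile normalisation none of the 3 passed (adjusted p = 0.0587, 0.106 and 0.0676), with UQCRQ down from 0.40 to 0.17 on the log2 scale. With scaling by total recovered reads the list median was 0.07 and 1 gene rose; COX6C (0.0769) and UQCRQ (0.0637) did not pass, and with median-of-ratios scaling UQCRQ (0.0647) and UQCRC1 (0.0553) did not. None of 35 ribosomal protein genes passed in limma (0 also when adjusted over the list alone), and RPL38, with the smallest p, measured 160 ± 1.7 and 188 ± 4.2 RPKM (adjusted p = 0.0677). It passed with voom on the recovered reads (adjusted p = 0.00859), but its log2 value ran from -0.07 to 0.26 over the 17 alternative settings. As a list the ribosomal protein genes were higher by camera (median 0.12, adjusted p = 0.000467, and adjusted p = 0.712 with an estimated correlation) with the authors' scaling. They were lower after quantile normalisation (adjusted p = 3.63e-09), on the lower side without passing with scaling by total recovered reads (0.435), and did not pass without TGF-β1 replicate 2 (0.0767).

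Lists that did not pass camera held changes in both directions or few changes. Of 27 glycolysis and hypoxia genes, 4 rose and 5 fell (8 and 5 adjusted over the list alone; median 0.04, mean -0.13, camera adjusted p = 0.790). BNIP3, ENO2 (-1.35), NDRG1 (-1.28), ADM (-1.12) and PFKFB3 (40.5 ± 0.66 to 23.8 ± 0.79 RPKM, -0.75) fell, and PFKP, a phosphofructokinase isoform, rose 1.82-fold to 41.7 ± 1.2 RPKM together with VEGFA (0.71), TPI1 (0.38) and PKM (0.33). The list passed as lower after quantile normalisation (adjusted p = 0.0481), and with scaling by total recovered reads 2 genes rose and 6 fell (median -0.12). PFKP and PFKFB3 did not pass without the variance trend (adjusted p = 0.0574 and 0.0649). Of 22 NRF2 and oxidative stress genes, PRDX1, a peroxiredoxin, rose 1.63-fold to 859 ± 25 RPKM, while SOD2, the mitochondrial superoxide dismutase, fell from 12.4 ± 2.6 to 4.27 ± 0.0019 RPKM (-1.42) and TXNRD1, thioredoxin reductase, from 42.8 ± 1.7 to 32.8 ± 1.2 RPKM (-0.38). Adjusted over the list alone, 5 rose and 3 fell, and camera gave adjusted p = 0.972 (median 0.10, mean -0.01, direction down). Scaled by total recovered reads, 1 rose and 5 fell (median -0.07). TXNRD1 lost its call whichever library was left out, with adjusted p values from 0.0644 to 0.159. Without the variance trend TXNRD1, PRDX1 and SOD2 did not pass (adjusted p = 0.18, 0.0812 and 0.0558). None of 23 fatty acid oxidation and peroxisome genes passed in limma (0 also when adjusted over the list alone; camera adjusted p = 0.405). The peroxisomal enzyme EHHADH came closest, at 3.09 ± 0.073 and 1.45 ± 0.16 RPKM (adjusted p = 0.0516), and passed with quantile normalisation (0.0485), upper-quartile scaling (0.0448), scaling by total recovered reads (0.0367) and voom (0.00105).

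Most markers of other cell types could not be tested, being under the expression filter or not found in the deposited table. Of the fibroblast, endothelial, immune and distal nephron markers 10, 9, 9 and 9 were found. None of these 4 lists passed camera. Of the fibroblast markers 3 of 13 could be tested, and FBLN1, a matrix fibulin, rose 1.55-fold to 28.1 ± 0.46 RPKM (camera adjusted p = 0.866, with 1 higher and 1 lower adjusted over the list alone). Of 13 endothelial markers 2 could be tested and neither passed (0 adjusted over the list alone). ESAM, an endothelial adhesion molecule, measured 0.486 ± 0.19 and 1.51 ± 0.91 RPKM (adjusted p = 0.226, and 0.0484 with voom; camera adjusted p = 0.325). Of 15 immune markers 4 could be tested, and CSF1R, the receptor for CSF1, rose 5.00-fold from 2.07 ± 0.032 to 10.3 ± 0.33 RPKM (camera adjusted p = 0.123, with 1 higher adjusted over the list alone). Of 17 distal nephron markers 2 could be tested. The sodium channel subunit SCNN1A fell from 3.07 ± 0.58 to 0.394 ± 0.22 RPKM (-2.01) and the aquaporin AQP3 went from 3 and 5 reads to 36 and 24 (1.69). Camera gave adjusted p = 0.866 for that list, and the same 2 genes passed when adjusted over the list alone. SCNN1A lost its call without control replicate 1 (adjusted p = 0.0601) or TGF-β1 replicate 2 (0.0529), and AQP3 whichever library was left out (0.0561 to 0.138). FBLN1 lost its call without TGF-β1 replicate 2 (log2 0.60). Without the variance trend FBLN1, SCNN1A and AQP3 did not pass (adjusted p = 0.0798, 0.0524 and 0.0651).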

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

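Voom on the recovered reads, the fit without a further pseudocount and the scaling by total recovered reads were chosen after seeing the data. FRMD6 stayed between 2.27 and 2.52 on the log2 scale under all 17 settings, with adjusted p values up to 0.0315, and MIR17HG passed under none of the 16 in which it was tested. The count of 1513 changed genes became 977 without the expression filter (297 lower), 424 without the variance trend (280 higher, 144 lower), 3359 with voom (2006 and 1353) and 634 at an absolute log2 fold change of at least 1. Leaving out each library in turn gave 574 to 1138 genes (395 to 842 higher, 179 to 297 lower), with fewer samples in each of these fits. Scaling by total recovered reads gave 655 higher and 883 lower genes, and 1153 of the 1513 genes were called under it. Voom shared 1412 of them, and called 3 further named genes. Of the 91 values checked for named genes, 36 lost their call without the variance trend, 22 without TGF-β1 replicate 2, 16 without TGF-β1 replicate 1, 16 without control replicate 1, 8 without control replicate 2 and 10 without the expression filter, where more genes were tested. After quantile normalisation the log2 values of SPARC (0.91 to 0.58), FASN (0.53 to 0.32), PRDX1 (0.70 to 0.44), SLBP (-0.43 to -0.71) and CDT1 (-0.37 to -0.62) changed by more than 1.5 times and kept their calls. None of the named genes that passed reversed its direction under these settings.

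Samples share only a replicate number: the deviations of replicates 1 and 2 from their group means correlated at 0.026 across genes between the groups. With the replicate number as a block 1344 genes changed (947 higher and 397 lower). Of the 91 values checked for named genes, 1 did not pass with that block, DSCC1 (adjusted p = 0.0599).

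With an estimated correlation in place of the preset one, camera gave adjusted p = 0.375 for SMAD targets, 0.439 for ligands and receptors, 0.438 for collagens, 0.712 for glycoproteins, 0.445 for matrix enzymes, 0.439 for contractile and for mesenchymal genes, 0.550 for epithelial, 0.439 for proximal tubule, for injury, for p53 and for ATF4 genes, 0.493 for YAP targets and for cholesterol genes, 0.386 for S phase and for interferon genes, 0.579 for oxidative phosphorylation and 0.712 for ribosomal proteins. That test rests on 2 residual degrees of freedom, which left it little power to pass any list. For SMAD targets, S phase and interferon genes the estimated correlation (0.0095, 0.0099 and -0.0028) was no larger than the preset 0.01. Their loss therefore does not come from correlation between genes. For lists with a larger estimate, such as ribosomal proteins (0.81), the degrees of freedom and the correlation cannot be told apart as reasons. With fry, which asks another question, adjusted p was 0.120 for glycoproteins, 0.118 for epithelial, 0.0677 for proximal tubule, 0.487 for injury, 0.0639 for YAP and for p53 targets, 0.101 for cholesterol, 0.156 for oxidative phosphorylation and 0.223 for ribosomal proteins. It was 0.0265 for microRNA biogenesis and 0.0381 for immune markers, which had not passed camera. Other lists kept their call by fry: SMAD targets (adjusted p = 0.00293), contractile genes (0.0310), matrix enzymes (0.0449) and ATF4 genes (0.0485). So did ligands and receptors, collagens, mesenchymal, S phase and interferon genes (fry adjusted p = 0.0265 for each). Among genes with a mean RPKM of at least 2, glycoproteins (0.0609) and epithelial genes (0.0734) did not pass, and without the filter injury genes did not (0.215). After quantile normalisation oxidative phosphorylation did not pass (0.116), glycolysis did (0.0481), and ribosomal proteins were lower (3.63e-09). With scaling by total recovered reads oxidative phosphorylation still passed as higher (0.0375), epithelial (0.109) and injury genes (0.0602) did not pass and ribosomal proteins were on the lower side (0.435). That scaling moved the median of all tested genes by -0.15, and those of lists that did not pass camera in step, from -0.09 to -0.24 for Hippo components (1 higher, 4 lower), from -0.11 to -0.29 for miR-17 family targets (8 and 5), from 0.03 to -0.14 for microRNA biogenesis (2 and 1), from -0.15 to -0.31 for growth arrest (5 and 3) and from -0.02 to -0.17 for fatty acid oxidation (0 and 1). Under it SMAD targets had 16 higher and 0 lower, collagens 9 and 1, contractile genes 13 and 1, mesenchymal genes 9 and 1, YAP targets 1 and 10 and interferon genes 0 and 6. The cause was not tested for these lists other than the ribosomal proteins and oxidative phosphorylation. Leaving out each library gave adjusted p values of 0.00511 to 0.0602 for epithelial, 0.00222 to 0.0706 for injury and 5.18e-07 to 0.0767 for ribosomal genes.

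Depth limits weakly expressed genes most: with 3330021 to 5440187 reads per library, ACTA2 and most markers of other cell types found in the deposited table had too few reads to test. For markers not found in that table nothing can be said of their reads.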

Other observations

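The 5 gene lists described first, the tests of shared reads in the CGB and LHB genes the tests with scaling by total recovered reads and those on the ribosomal and oxidative phosphorylation lists apart were chosen only after the results were seen. For the seed test and the test of the chromosome region, the requirement that a bootstrap interval clear the bound was also added after a first value was known.

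Several ligand and receptor families held members that rose and members that fell, and none of these 5 lists passed camera. In the Wnt family, 4 of 18 tested genes rose and 3 fell (4 and 5 adjusted over the list alone). The non-canonical ligands WNT5A and WNT5B rose from 0.384 ± 0.0068 to 2.19 ± 0.087 RPKM and from 0.634 ± 0.023 to 4.80 ± 0.20 RPKM, with WNT9A and FZD2. The antagonist DKK1 (15.3 ± 0.22 to 6.56 ± 0.87 RPKM), WNT7B and the coreceptor gene LRP5 fell. Among 20 semaphorins, plexins and partners, 6 rose and 5 fell (6 and 8 adjusted over the list alone). Their median log2 was -0.17 with the authors' scaling and -0.31 with scaling by total recovered reads. SEMA7A rose 5.05-fold to 39.4 ± 2.6 RPKM and PLXND1 2.38-fold to 59.3 ± 2.9 RPKM, while SEMA6B fell from 9.54 ± 1.6 to 2.78 ± 0.43 RPKM. Among 21 Notch pathway genes, JAG1, HES1 (2.74-fold) and LFNG rose, and JAG2 (5.85 ± 0.30 to 2.62 ± 0.22 RPKM) and DTX3L fell (4 and 2 adjusted over the list alone).

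Among 11 integrin genes, ITGA5, ITGAV (2.39-fold to 15.1 ± 0.54 RPKM) and ITGB5 rose, and ITGB4 (2.71 ± 0.41 to 0.892 ± 0.17 RPKM) and ITGB2 fell. Adjusted over the list alone 6 were higher and 3 lower, and the median log2 was 0.42 with the authors' scaling and 0.24 with scaling by total recovered reads. Among 14 IL-6 family cytokines and receptors, 3 rose, IL11 and LIF among them, and IL6R fell (3 and 1 adjusted over the list alone). Camera gave adjusted p = 0.983, 0.527, 0.418, 0.370 and 0.363 for the Wnt, semaphorin, Notch, integrin and IL-6 lists.

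The CGB and LHB genes of chromosome 19 were called higher together: CGB2, CGB3, CGB5, CGB7, CGB8 and LHB passed, and CGB1 had too few reads to test. For LHB, reads that match another CGB or LHB gene exactly are argued against, since 0.520% of its 50-base words occur in another family member. Reads placed with mismatches and reads shared with pseudogenes of the cluster were not tested. For the 5 CGB genes the share of such words was 11.6% in CGB7 and 54.4% or more in the others. A rise of each gene and a rise of fewer copies with shared reads therefore cannot be told apart while the counting rule is unknown. A rise of the whole region cannot be told apart either, because the 18 other tested genes within 100 kb had a median log2 fold change of 0.187 with a bootstrap interval of 0.007 to 1.03. That median spans 10 named coding neighbours (median 0.10, 1 called), 5 unnamed genes in or beside the cluster (median 2.77, 4 called), and RN7SL708P (1.14), ENSG00000260366 (-0.41) and ENSG00000267898 (0.09), none called, and a response of the cluster to TGF-β1 stays open as a hypothesis.

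More genes were called higher (67.1%) than lower. The authors' scaling is a possible explanation. Higher genes made up 62.2% of the calls with median-of-ratios scaling, 59.7% with upper-quartile scaling and 50.4% after quantile normalisation. When each library was scaled by its total of recovered reads the share was 42.6%. That last scaling moved the median of all tested genes by -0.15, which by itself lowers the share, so the authors' scaling was not tested by it. Reads taken up by the called genes might explain why the 2 scalings differ: called-higher genes held 15.7% and 15.8% of reads in controls and 23.5% and 23.9% with TGF-β1. Without the called genes, the difference between groups in library size over recovered reads was 5.04%, against 13.4% with them, which lay between the bounds set for and against and used genes picked by calls made under the authors' scaling. Whether TGF-β1 raises more genes than it lowers therefore stays open.

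Ribosomal protein and oxidative phosphorylation genes were slightly higher with the authors' scaling, with a joint median log2 fold change of 0.145 over 66 genes, and -0.061 (interval -0.09 to 0.00014) after a loess correction for exon length and expression level. For the 35 ribosomal protein genes alone it was -0.104 after that correction, so a trend with length and level could account for their small rise. For the 31 oxidative phosphorylation genes it was 0.083 (interval 0.03 to 0.14), between the bounds set for and against, so that trend and a rise with TGF-β1 cannot be told apart. Scaling by total recovered reads gave medians of -0.059 and 0.066 for the 2 lists, but it moved the median of all tested genes by -0.15, which by itself fixes that outcome, so the authors' scaling was not tested by it. Under that scaling the oxidative phosphorylation list was still higher than other genes by camera (adjusted p = 0.0375).

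A further hypothesis was that TGF-β1 lowers the activity of miR-17 and miR-20a broadly enough to raise the transcripts that carry their seed match. FRMD6 holds 1 such match in its 3′ UTR of 2698 bases, at position 161 from the UTR's start, and it is an 8-base match. Across genes, which are not independent replicates, the 2862 genes with a match and the 8650 without had medians of -0.01 and 0.03, which differed by -0.00949 after centring within bins of UTR length and expression (bootstrap interval -0.024 to 0.0029, two-sided permutation p = 0.102). The difference exceeded that of 30.5% of the 416 control words, and the interval lies below their 95th percentile of 0.024; for the 613 genes with the 8-base match the centred difference was -0.021 (permutation p = 0.109). The values argue against a broad rise of seed-matched transcripts, and a change confined to a few targets such as FRMD6 remains untested here, as does regulation of FRMD6 without the microRNAs.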
